A study of Arabidopsis thaliana with 21 samples.

How the data were processed

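The samples were aerial parts of Arabidopsis thaliana plants of the Col-0 background and of camta mutants in it. Per the labels, total RNA was extracted with RNeasy kits, amplified with MessageAmp, labelled with biotin and hybridized to arrays, with 3 biological replicates per group. The table deposited by the authors holds log2 values that were normalized with GCRMA, and limma was used, per the submitters' processing notes; the versions of GCRMA and limma are not given in the sources used here. The log2 values were used as deposited. All 21 columns of the table were matched to samples by their names, and the groups were taken from the labels.

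Of 22810 probe sets, 64 controls were left out of the tests, and 22746 were tested with no filter on low values. Genes were named from a table of probe sets and genes. It listed 14016 of the probe sets, 13523 with 1 gene and 493 with several, and the other 8730 were tested without a name. For 13436 the single gene was matched to the RefSeq annotation. The 13364 genes named include 148 with several probe sets, and such a gene is given by the probe set with the highest mean over all arrays. A locus with no probe set named here was not analysed here. No coordinates are given, since the sequences of the probes were not used here. The precision of every value is limited by the number of arrays, 3 per group.

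A linear model of 7 group means was fitted to all 21 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 14 residual degrees of freedom and 0.954 prior ones. From it 12 differences between groups were tested, two-sided, with p-values adjusted by the Benjamini-Hochberg method over the probe sets of each comparison; a probe set was called at an adjusted p under 0.05. The comparisons, this threshold, 20 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists held 342 entries, of which 56 had a probe set named here and are called measured below. The others were not looked up among the 8730 probe sets without a name, so the array may still hold them. Of the lists 18 had a measured member, and none of the flower markers or of the genes of abscisic acid response was measured. The 5 lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation and with fry as alternatives. Of 60 list tests 25 were called, and 14 with an estimated correlation. All of the calls of the COR and CBF regulon list were held with an estimated correlation, as were those of the lists of pattern-triggered immunity and flavonoid synthesis except where another adjusted p is given. Of list members, a count adjusted over the list alone is given beside that over all probe sets.

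The named genes were fixed genes where measured (of 16, only COR15A was), the 8 largest rises and 8 largest falls of each comparison among called probe sets of 1 gene whose groups did not overlap (5 and 5 for the interaction and between mutants), up to 4 called members of each list with the largest changes, and up to 2 members with the highest levels for a list not moved. The text gives a part of them. Samples were compared with the others of their group by correlation over all probe sets, and no pair of arrays held the same values. The replicate numbers of the labels were checked for pairing: 16 of 21 arrays had their closest residuals with arrays of their own number, so a block for the number was tried.

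The alternatives were quantile normalization, centring on the median, filters on a level of 4, trended and robust variances, array weights, the replicate block, only the arrays of the groups compared, a 2-fold threshold, an adjusted p under 0.01, 1 probe set per gene, and leaving out each array in turn. After the data were seen, the actin 3′ to 5′ difference as a covariate, a fit without replicate 2 of camta1/2/3 at each temperature, and tests of 30 gene families were added. The fit was tested on simulated data made from permuted residuals with 200 changed probe sets. Between camta1/2/3 and WT at 22 °C it called 23.9% of log2 changes of 0.5, 70.1% of changes of 1 and 98.5% of changes of 2, and 9 of its 137 calls were unchanged probe sets. For the interaction the shares were 16.4%, 34.3% and 87.9%, and 4 of 96 calls were unchanged. The real comparisons called 5342 and 447 probe sets. The adjusted threshold depends on how many probe sets change, so these shares do not carry over to the real comparisons.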

Results

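Transcript levels were measured on 21 arrays of 22810 probe sets in the aerial parts of Arabidopsis thaliana plants of the Col-0 background, grown on soil at 22 °C for 3 weeks under a 12 h photoperiod. The arrays formed 7 groups of 3 replicates. At 22 °C these were the wild type (WT), the double mutants camta1/2, camta1/3 and camta2/3 and the triple mutant camta1/2/3, and after 24 h at 4 °C they were WT and camta1/2/3. The CAMTA genes encode calmodulin-binding transcription activators. The mutated genes had no probe set named here, so the genotypes could not be checked on the arrays. Deposited log2 values ran from 2.17 to 14.27, the medians of the arrays from 4.86 to 5.01, and 59.8% to 60.7% of the probe sets of an array lay over 4. On a principal component analysis, the first component (40.9% of the variance) parted the arrays at 4 °C from those at 22 °C, and the second (31.2%) parted camta1/2/3 from WT. Levels below are log2 means ± SD with n = 3 arrays per group, and a gene is said to rise or fall where its adjusted p was under 0.05. The values came without detection calls, so a difference from a group at about 3 or lower is only a lower bound.

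The difference between the 3′ and 5′ control probe sets of actin, which widens as RNA breaks down or its copies shorten, was not the same in all groups. It was 2.23 ± 0.21 in WT, 2.09 ± 0.05 in camta1/2, 2.48 ± 0.26 in camta1/3, 2.62 ± 0.16 in camta2/3 and 2.90 ± 0.13 in camta1/2/3 at 22 °C (log2, n = 3 each). At 4 °C it was 2.00 ± 0.62 in WT and 3.11 ± 1.0 in camta1/2/3, where replicate 2 stood at 4.25.

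**Figure D1:**
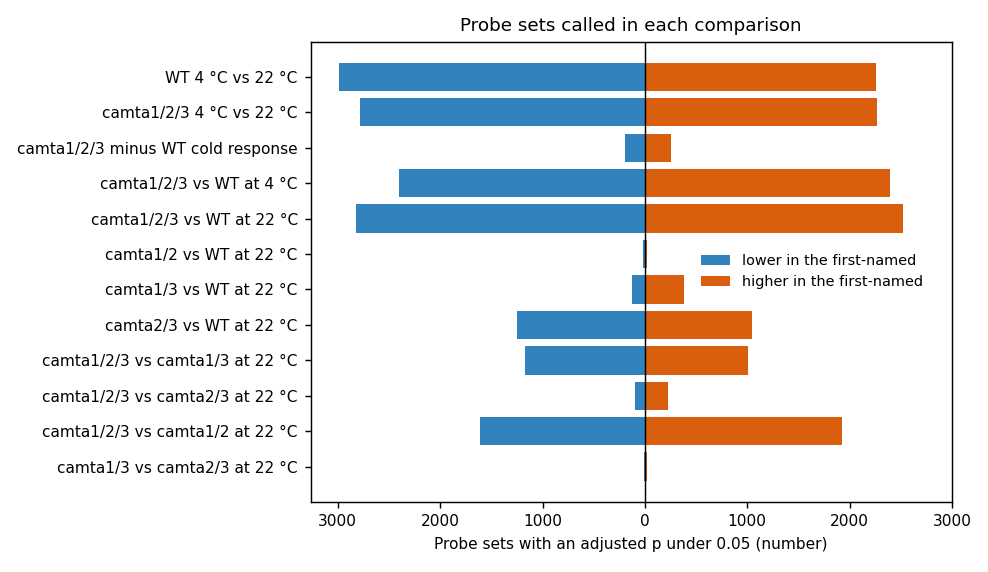
Number of probe sets with an adjusted p under 0.05 in each of the 12 comparisons, with those lower in the first-named group to the left of 0 and those higher to the right. The counts run from 24 for camta1/3 against camta2/3 to 5342 for camta1/2/3 against WT at 22 °C.

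The first question was what 24 h at 4 °C did to the WT. Cold-regulated genes rose steeply. COR15A (AT2G42540), which encodes a chloroplast-targeted cold-regulated protein, rose 8.42-fold from 9.00 ± 0.75 to 12.07 ± 0.76. The dehydrin genes LTI30 (AT3G50970) and COR47 (AT1G20440) rose from 7.46 ± 1.47 to 13.32 ± 0.20 and from 8.66 ± 0.65 to 13.13 ± 0.32. LEA4-5 (AT5G06760), a late embryogenesis abundant gene, went from 2.48 ± 0.11 to 8.08 ± 0.71, and the U-box ubiquitin ligase gene PUB19 (AT1G60190) from 3.93 ± 0.02 to 9.07 ± 0.57. Among the falls, the expansin gene EXPA8 (AT2G40610) went from 7.87 ± 0.65 to 3.58 ± 0.48 and AT1G13650 from 9.78 ± 0.36 to 3.65 ± 0.00.

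All 6 measured members of the list of COR and CBF regulon genes rose in WT, 6 when adjusted over the list alone, among them COR27 (AT5G42900) from 4.02 ± 0.18 to 9.16 ± 0.55 (list test, adjusted p = 1.74e-09). Of 6 photosynthesis genes 4 fell and 2 did not pass (5 fell when adjusted over the list alone). The light-harvesting antenna gene LHCB4.2 (AT3G08940) went from 12.45 ± 0.16 to 10.29 ± 0.24 and the Rubisco activase gene RCA (AT2G39730) from 13.66 ± 0.17 to 12.86 ± 0.11. That list was lower (adjusted p = 0.000175), a call lost at an adjusted p = 0.0846 with an estimated correlation. All 5 genes of ribosome biogenesis rose, 5 when adjusted over the list alone, AT3G15460 from 6.56 ± 0.40 to 7.66 ± 0.16 and AT5G14520 from 8.78 ± 0.16 to 9.62 ± 0.18 (adjusted p = 0.000773, and adjusted p = 0.0799 with an estimated correlation).

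Both clock genes rose, 2 when adjusted over the list alone, with GI (AT1G22770) going from 8.63 ± 0.17 to 9.86 ± 0.12. Of 3 CAMTA family genes 2 rose (3 when adjusted over the list alone): AT1G67310 went from 6.38 ± 0.06 to 7.56 ± 0.57 and AT3G16940 from 6.53 ± 0.12 to 7.44 ± 0.15. Of the early cold-induced transcription factors, the 1 measured rose, 1 when adjusted over the list alone: the zinc finger gene STZ (AT1G27730) went from 5.43 ± 0.84 to 7.73 ± 0.50. Both genes of cell expansion fell, 2 when adjusted over the list alone, EXPA8 and EXO (AT4G08950), the latter from 6.62 ± 0.33 to 5.23 ± 0.55. Of 5 flavonoid genes 2 rose and 3 did not pass (2 rose when adjusted over the list alone), with the flavonoid 3-O-glucosyltransferase gene UGT78D2 (AT5G17050) going from 7.84 ± 0.18 to 10.12 ± 0.13. That list did not pass (adjusted p = 0.138), and its median, −0.29, had another sign than its mean, 0.36, and its test. Of 3 genes of glucosinolate synthesis 2 fell and 1 did not pass, and 2 fell when adjusted over the list alone. Of 3 genes of endoplasmic reticulum folding 1 rose and 2 fell, and the counts were the same when adjusted over the list alone. The 1 gene of starch breakdown, DPE1 (AT5G64860), fell from 7.84 ± 0.31 to 7.30 ± 0.08, and 1 of 3 jasmonate and ethylene genes, THI2.1 (AT1G72260), from 3.84 ± 0.20 to 3.45 ± 0.03; each count held when adjusted over the list alone. Of 3 root markers, included as a sign of other tissue, PYK10 (AT3G09260) fell from 7.97 ± 0.48 to 6.40 ± 0.05 and 2 did not pass, with 1 fall when adjusted over the list alone.

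The few immunity genes measured here showed no called change in WT at 4 °C: 0 of 5 genes of pattern-triggered immunity passed, and 0 when adjusted over the list alone (list test, adjusted p = 0.423). The receptor-like cytoplasmic kinase gene BIK1 (AT2G39660) stood at 5.32 ± 0.15 at 22 °C and 5.51 ± 0.17 at 4 °C. Likewise 0 of 2 genes of salicylic acid and N-hydroxypipecolic acid synthesis and control, 0 of 1 of salicylic acid response, 0 of 3 of heat shock and 0 of 2 of senescence passed, and 0 of each when adjusted over the list alone.

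By limma, 5250 probe sets were called in WT, 2259 higher and 2991 lower at 4 °C, of which 914 and 1124 differed at least 2-fold. The split depended on the scaling: 43.0% were higher, but 48.3% with quantile normalization and 52.5% with each array centred on its median. With only the 6 arrays of both groups in the fit 3131 were called. Of the list genes counted above, AT1G67310, STZ, THI2.1, DPE1, EXO, the flavonoid gene AT5MAT, CRT1b and BZIP60 of endoplasmic reticulum folding and NRPA1 and AT1G52930 of ribosome biogenesis then lost their call. Among the 6 fits without 1 array, both glucosinolate genes called as lower lost their call in 5 (highest adjusted p 0.138 for AT2G31790 and 0.0982 for BCAT4), CRT1b in 5 (0.179), BZIP60 in 4 (0.105), ATERDJ3B of the same folding list in 2 (0.0683), DPE1 in 4 (0.159), NRPA1 in 4 (0.121), the photosynthesis gene PRK in 3 (0.0751) and THI2.1 in 1, without WT replicate 3 at 22 °C (0.0521). With actin as a covariate AT2G31790 lost its call (0.0540).

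The same question was asked of the triple mutant. COR15A rose 149-fold in camta1/2/3, from 5.08 ± 0.46 to 12.30 ± 0.23, COR15B (AT2G42530) rose from 7.87 ± 0.76 to 12.54 ± 0.50, LTI30 from 6.92 ± 1.33 to 13.15 ± 0.17 and COR47 from 7.83 ± 0.61 to 12.69 ± 0.40. AT1G16850 rose from 2.42 ± 0.28 to 9.87 ± 0.11. EXPA8 fell from 7.42 ± 0.51 to 3.79 ± 0.69, AT5G19120 from 8.16 ± 0.08 to 3.73 ± 0.47 and the defensin gene PDF1.4 (AT1G19610) from 8.13 ± 0.09 to 4.91 ± 0.61.

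All 6 COR and CBF regulon genes rose in the triple mutant (6 when adjusted over the list alone, list test adjusted p = 4.05e-11). Of 6 photosynthesis genes 5 fell (6 when adjusted over the list alone), with LHCB4.2 going from 11.96 ± 0.35 to 10.38 ± 0.13 (adjusted p = 6.61e-05, and adjusted p = 0.0674 with an estimated correlation). All 5 genes of ribosome biogenesis rose (5 when adjusted over the list alone), AT3G15460 from 5.62 ± 0.45 to 7.09 ± 0.16 (adjusted p = 0.000582, and adjusted p = 0.0674 with an estimated correlation). All 3 genes of glucosinolate synthesis fell, 3 when adjusted over the list alone; BCAT4 (AT3G19710), which starts methionine chain elongation, went from 9.06 ± 0.58 to 7.49 ± 0.20 and the glucosyltransferase gene AT2G31790 from 7.22 ± 0.17 to 6.04 ± 0.45. In the list of pattern-triggered immunity 2 of 5 genes rose, 1 fell and 2 did not pass, with the same counts when adjusted over the list alone. BIK1 went from 7.37 ± 0.18 to 7.89 ± 0.13, PUB22 (AT3G52450) from 2.63 ± 0.18 to 3.56 ± 0.51 and WRKY53 (AT4G23810) from 7.30 ± 0.12 to 5.09 ± 1.0 (list test, adjusted p = 0.0802). Of the 3 root markers PYK10 fell from 8.83 ± 0.43 to 7.14 ± 0.18, with 1 fall when adjusted over the list alone. UGT78D2 rose from 6.64 ± 0.09 to 9.43 ± 0.16, as 1 of 5 flavonoid genes (1 when adjusted over the list alone, list test adjusted p = 0.0594).

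In camta1/2/3, 5053 probe sets were called between 4 °C and 22 °C, 2266 higher and 2787 lower (44.8% higher, but 50.8% with each array centred on its median). Of these, 3028 were called in the same direction in WT and 25 in the opposite one. The fit on the 6 arrays alone called 2447, among them 0 of the 3 glucosinolate genes, 0 of the 3 immunity genes, 1 of the 5 photosynthesis genes and 1 of the 5 ribosome biogenesis genes. Among the 6 fits without 1 array, NRPA1 lost its call in 5 (highest adjusted p 0.195), PRK in 4 (0.0917), WRKY53 in 4 (0.127), AT5G14520 in 3 and AT1G52930 in 1 (0.0510).

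**Figure D2:**
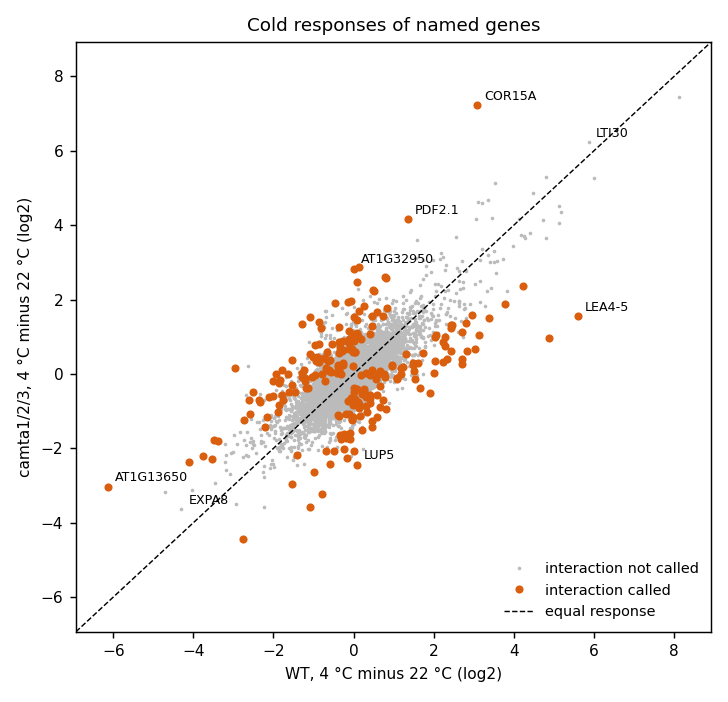
Cold response of each named gene (4 °C minus 22 °C, difference of log2 means, n = 3 arrays per group) in WT on the x axis and in camta1/2/3 on the y axis, with an equal response on the dashed line. Orange points mark genes whose responses differed between the genotypes, such as COR15A, at 3.07 in WT and 7.22 in camta1/2/3.

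Which genes answered cold differently in the triple mutant was asked with the interaction of genotype and temperature. COR15A gained 4.15 ± 0.80 (log2 difference ± SE, n = 3 arrays in each of 4 groups) more in camta1/2/3 than in WT, since it started lower at 22 °C and reached a like level at 4 °C. The defensin gene PDF2.1 (AT2G02120) gained 2.80 ± 0.31 more, reaching 7.55 ± 0.18 from 3.39 ± 0.16 in camta1/2/3. For 3 other genes the levels at 22 °C lay at the floor in both genotypes, so only their levels at 4 °C can be compared: the subtilase family gene AT1G32950, at 5.01 ± 0.32 in camta1/2/3 against 2.17 ± 0.00 in WT, LEA4-5, at 3.99 ± 0.51 against 8.08 ± 0.71, and AT2G24560, at 3.13 ± 0.43 against 7.05 ± 1.0.

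By list, 1 of 6 COR and CBF regulon genes, COR15A, passed the interaction test (1 when adjusted over the list alone) and 1 of 3 jasmonate and ethylene genes, THI2.1, at 0.62 ± 0.14 (1 when adjusted over the list alone). Of the other lists 0 genes passed over all probe sets. Adjusted over the list alone, 3 of 3 genes of glucosinolate synthesis, 2 of 3 CAMTA family genes and 1 gene each of flavonoid synthesis, the clock and endoplasmic reticulum folding passed as lower, and 1 gene each of salicylic acid synthesis and control, pattern-triggered immunity and flavonoid synthesis as higher. The lowest adjusted p of a list test was 0.538.

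Of the 914 probe sets that rose at least 2-fold in WT, 65 (7.11%) rose less in camta1/2/3 by the interaction test and 8 rose more, and 724 (79.2%) were also called higher in camta1/2/3. Of the 1124 that fell at least 2-fold, 96 (8.54%) fell less and 6 fell more, and 826 (73.5%) were also called lower. The median response of those that rose was 1.49 in WT and 1.16 in camta1/2/3, and of those that fell −1.38 and −1.01 (log2). These shares count called interactions, and a probe set without a call may still have responded less. Choosing by the WT response favours the smaller response in the mutant. Chosen by the mean response of both genotypes, 42 of 819 (5.13%) rose less and 28 rose more, and 58 of 962 (6.03%) fell less and 30 fell more.

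The interaction was called for 447 probe sets, 254 positive and 193 negative; 275 were called without WT replicate 2 at 22 °C and 188 on the 12 arrays alone. THI2.1 lost its call in 10 of 12 fits without 1 array (highest adjusted p 0.0718) and with a replicate block (0.0523), and the share of 8.54% became 5.31% without WT replicate 2 at 22 °C and 5.58% without WT replicate 3 at 4 °C.

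**Figure D3:**
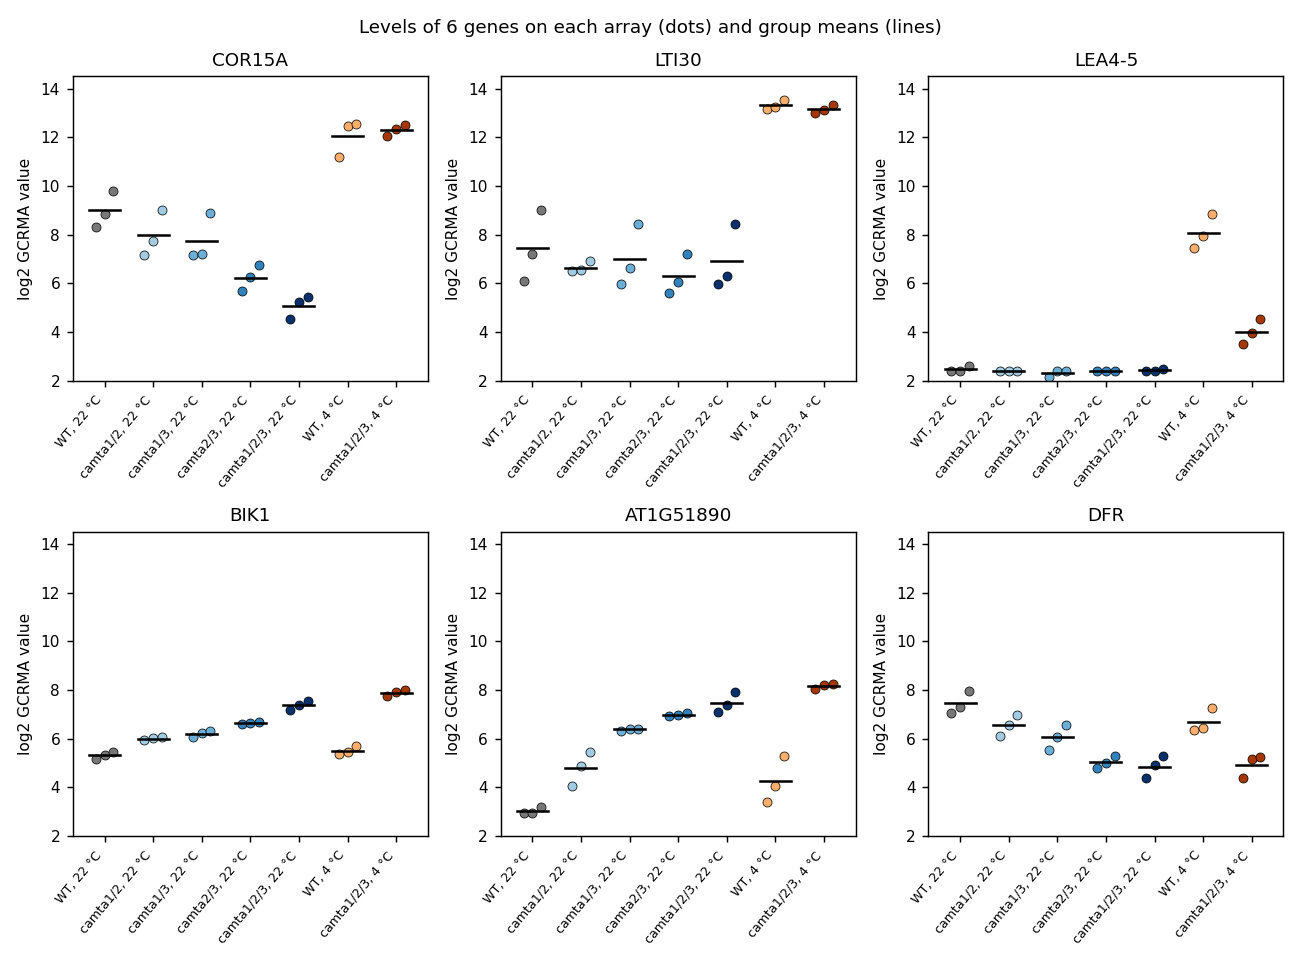
Log2 GCRMA values (y axis) of 6 genes in the 7 groups (x axis), with a dot for each of the 3 arrays of a group and a line at their mean. COR15A at 22 °C lies at 9.00 in WT and 5.08 in camta1/2/3 but near 12 in both at 4 °C, and BIK1 lies at 5.32 in WT and 7.37 in camta1/2/3 at 22 °C.

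At 4 °C, camta1/2/3 was compared with WT. Among the largest differences, the subtilase gene SBT3.3 (AT1G32960) stood at 10.94 ± 0.34 against 5.87 ± 1.08, AT3G48640 at 10.27 ± 0.56 against 4.44 ± 0.43, and the TIR-domain genes AT1G72900 and AT1G72920 at 8.98 ± 0.26 against 4.09 ± 0.38 and 8.14 ± 0.76 against 3.62 ± 0.12. Lower in the mutant were the thionin family gene AT1G66100, at 3.76 ± 0.72 against 8.76 ± 0.40, LEA4-5, at 3.99 ± 0.51 against 8.08 ± 0.71, the expansin-like gene EXLA1 (AT3G45970), at 5.38 ± 0.12 against 9.43 ± 0.72, and the sugar transporter gene SWEET4 (AT3G28007), at 4.77 ± 0.09 against 7.79 ± 0.20.

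Of 5 genes of pattern-triggered immunity 4 were higher at 4 °C (4 when adjusted over the list alone), with BIK1 at 7.89 ± 0.13 against 5.51 ± 0.17 and WRKY22 (AT4G01250) at 4.79 ± 0.56 against 3.32 ± 0.80 (list test, adjusted p = 3.86e-05). Both genes of salicylic acid and N-hydroxypipecolic acid synthesis and control were higher (2 when adjusted over the list alone): AT5G52810 stood at 8.25 ± 0.12 against 6.05 ± 0.24 and SAG101 (AT5G14930) at 5.81 ± 0.21 against 4.65 ± 0.42. The 1 salicylic acid response gene, the glutaredoxin gene GRX480 (AT1G28480), stood at 7.98 ± 0.14 against 6.27 ± 0.40 (1 when adjusted over the list alone). All 5 flavonoid genes were lower (5 when adjusted over the list alone), among them the dihydroflavonol reductase gene DFR (AT5G42800), at 4.93 ± 0.48 against 6.70 ± 0.50 (list test, adjusted p = 0.000183). All 3 genes of glucosinolate synthesis were lower (3 when adjusted over the list alone), with BCAT4 at 7.49 ± 0.20 against 10.21 ± 0.15 and AT2G31790 at 6.04 ± 0.45 against 8.08 ± 0.03. Of 6 COR and CBF regulon genes 0 passed and 0 when adjusted over the list alone, with COR15B at 12.54 ± 0.50 against 12.56 ± 0.33 (list test, adjusted p = 0.488). The actin difference moved with these groups, 3.11 ± 1.0 in camta1/2/3 against 2.00 ± 0.62 in WT, and with it as a covariate 2692 probe sets were called, 2432 of them among the original ones, and GRX480 (adjusted p = 0.0567) and WRKY22 (0.0802) were not.

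In all, 4800 probe sets differed between the genotypes at 4 °C, 2394 higher and 2406 lower in camta1/2/3 (49.9% higher, but 45.0% with quantile normalization and 42.5% with each array centred on its median). At least 2-fold differences were 1120 higher and 682 lower. On the 6 arrays alone 2014 were called, among them 1 of the 4 immunity genes (BIK1), 2 of the 5 flavonoid genes, AT5G52810 but not SAG101, and all 3 glucosinolate genes. EFR of the immunity list and the flavonoid gene AT4G14090 each lost their call in 3 of 6 fits without 1 array (highest adjusted p 0.0838 and 0.0601).

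At 22 °C the triple mutant differed from WT as widely. CCOAMT (AT1G67980), named as a caffeoyl-CoA methyltransferase gene, stood higher, at 8.55 ± 0.33 against 3.36 ± 0.11, the leucine-rich repeat kinase gene AT1G51890 at 7.47 ± 0.40 against 3.05 ± 0.14, and AT3G28510 at 7.86 ± 0.38 against 2.85 ± 0.00. COR15A stood 15.1-fold lower, at 5.08 ± 0.46 against 9.00 ± 0.75. AT1G66100 was at 5.05 ± 1.68 against 10.67 ± 0.65 and TBL26 (AT4G01080) at 2.30 ± 0.07 against 6.06 ± 0.65.

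Of 5 genes of pattern-triggered immunity 3 were higher at 22 °C and 2 did not pass (4 higher when adjusted over the list alone), with BIK1 at 7.37 ± 0.18 against 5.32 ± 0.15, WRKY53 at 7.30 ± 0.12 against 4.08 ± 1.47 and WRKY22 at 4.14 ± 0.37 against 2.85 ± 0.08 (list test, adjusted p = 0.000318). SAG101 and AT5G52810 were higher, 2 of 2 genes of salicylic acid and N-hydroxypipecolic acid synthesis and control (2 when adjusted over the list alone), and so was GRX480, at 7.53 ± 0.28 against 5.65 ± 0.59 (1 of 1, and 1 when adjusted over the list alone). Of 5 flavonoid genes 4 were lower (4 when adjusted over the list alone): DFR stood at 4.86 ± 0.45 against 7.45 ± 0.47, the anthocyanin glycosyltransferase gene UF3GT (AT5G54060) at 4.69 ± 0.10 against 6.89 ± 0.59 and UGT78D2 at 6.64 ± 0.09 against 7.84 ± 0.18 (list test, adjusted p = 0.000318). All 3 genes of glucosinolate synthesis were lower (3 when adjusted over the list alone), with BCAT4 at 9.06 ± 0.58 against 10.99 ± 0.09. Of 3 jasmonate and ethylene genes 2 were lower (2 when adjusted over the list alone), with the defensin gene PDF1.2 (AT5G44420) at 3.89 ± 0.26 against 6.09 ± 0.70. Of 6 COR and CBF regulon genes 2 were lower, COR15A and COR15B (2 when adjusted over the list alone, list test adjusted p = 0.0877). GI was higher, at 9.62 ± 0.13 against 8.63 ± 0.17, as was the senescence-associated transcription factor gene WRKY6 (AT1G62300), at 7.03 ± 0.14 against 4.50 ± 0.69. The actin difference moved with these groups too, 2.90 ± 0.13 against 2.23 ± 0.21, and with it as a covariate 4565 probe sets were called, 4227 of them among the original ones, and COR15B (adjusted p = 0.0868) and the glucosinolate gene UGT74B1 (0.0901) were not.

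Between camta1/2/3 and WT at 22 °C, 5342 probe sets differed, 2521 higher and 2821 lower, though at least 2-fold differences were 1176 higher and 973 lower. On the 6 arrays alone 3252 were called, without WRKY53, COR15B, UGT74B1, THI2.1 or the flavonoid gene AT4G14090. COR15B also lost its call in 5 of 6 fits without 1 array (highest adjusted p 0.204) and UGT74B1 in 4 (0.116).

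The double mutants were compared with WT at 22 °C next. In camta1/2, BIK1 was higher than in WT, at 6.01 ± 0.07 against 5.32 ± 0.15, the receptor-like kinase gene AT5G59670 stood at 7.74 ± 0.11 against 5.90 ± 0.75 and AT1G49050 at 7.31 ± 0.26 against 6.01 ± 0.11. AT3G43270 was lower, at 5.35 ± 0.04 against 6.68 ± 0.25. COR15A was at 7.99 ± 0.95 against 9.00 ± 0.75 (adjusted p = 0.734). Pattern-triggered immunity had 1 of 5 genes higher, BIK1 (2 when adjusted over the list alone, list test adjusted p = 0.00451), and 0 of 5 flavonoid genes passed (4 lower when adjusted over the list alone, list test adjusted p = 0.000146), DFR standing at 6.55 ± 0.44 against 7.45 ± 0.47. The actin difference was 2.09 ± 0.05 against 2.23 ± 0.21. Only 37 probe sets were called, 23 higher and 14 lower, and by limma 0 on the 6 arrays alone, where 1491 had an unadjusted p under 0.05. The count was 279 without WT replicate 1 and 22 without WT replicate 2, and 7 without camta1/2 replicate 2 and 141 without replicate 3. The call of BIK1 was lost without WT replicate 2 or camta1/2 replicate 2 (highest adjusted p 0.0931), that of AT5G59670 in 4 fits without 1 array (0.135) and with a replicate block (0.0598), and that of AT3G43270 in 3 (0.109).

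In camta1/3, AT1G51890 was higher than in WT, at 6.38 ± 0.05 against 3.05 ± 0.14, AT3G28510 stood at 5.59 ± 0.64 against 2.85 ± 0.00, AT1G10340 at 7.48 ± 0.62 against 5.02 ± 0.52 and BIK1 at 6.21 ± 0.12 against 5.32 ± 0.15. The jacalin-related lectin gene JAL23 (AT2G39330) was lower, at 4.48 ± 0.17 against 6.53 ± 0.72, and TBL26 was at 4.34 ± 0.36 against 6.06 ± 0.65. COR15A stood at 7.76 ± 0.97 (adjusted p = 0.394). Only BIK1 of the 5 genes of pattern-triggered immunity passed (1 higher, and 2 when adjusted over the list alone, list test adjusted p = 0.00542). Flavonoid synthesis had 2 of 5 genes lower (4 when adjusted over the list alone, list test adjusted p = 3.39e-05), UF3GT at 5.34 ± 0.50 against 6.89 ± 0.59 and UGT78D2 at 7.27 ± 0.31 against 7.84 ± 0.18. Actin control probe sets differed by 2.48 ± 0.26 against 2.23 ± 0.21, and with it as a covariate UF3GT (adjusted p = 0.0552) and UGT78D2 (0.0599) lost their calls. In all 502 probe sets were called, 379 higher and 123 lower, but 1 on the 6 arrays alone, AT1G51890 being the 1 of the genes named here that kept its call. The count was 232 without WT replicate 2, 282 without WT replicate 3, 169 without camta1/3 replicate 2 and 265 without replicate 3; UF3GT and UGT78D2 lost their calls in 4 and 5 fits without 1 array (highest adjusted p 0.211 and 0.161), and UF3GT with a replicate block (0.0617).

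In camta2/3 the changes were wider. AT1G51890 was higher than in WT, at 6.99 ± 0.05 against 3.05 ± 0.14, AT3G48640 stood at 6.69 ± 0.40 against 2.88 ± 0.21 and CCOAMT at 6.82 ± 0.38 against 3.36 ± 0.11. TBL26 was lower, at 2.67 ± 0.25 against 6.06 ± 0.65, and COR15A was 6.77-fold lower, at 6.24 ± 0.55 against 9.00 ± 0.75 (adjusted p = 0.00506). In pattern-triggered immunity 2 of 5 genes were higher (3 when adjusted over the list alone), BIK1 at 6.66 ± 0.05 and WRKY53 at 6.88 ± 0.20 (list test, adjusted p = 0.00112). Both genes of salicylic acid and N-hydroxypipecolic acid synthesis and control were higher (2 when adjusted over the list alone), with SAG101 at 5.77 ± 0.18 against 4.59 ± 0.20. In flavonoid synthesis 4 of 5 genes were lower (4 when adjusted over the list alone), with DFR at 5.05 ± 0.24 against 7.45 ± 0.47 and UGT78D2 at 6.80 ± 0.13 against 7.84 ± 0.18 (list test, adjusted p = 5.85e-06). All 3 genes of glucosinolate synthesis were lower (3 when adjusted over the list alone), with BCAT4 at 9.62 ± 0.27 against 10.99 ± 0.09. Their actin 3′ to 5′ difference was 2.62 ± 0.16 against 2.23 ± 0.21, and 2075 probe sets were called with it as a covariate, without UGT74B1 of the glucosinolate genes (adjusted p = 0.0590). Without it 2301 were called, 1048 higher and 1253 lower (45.5% higher, but 50.7% with quantile normalization, and 576 higher against 373 lower at 2-fold), and 1485 without WT replicate 3 and 1262 on the 6 arrays alone, where COR15A (adjusted p = 0.0557), WRKY53 (0.141), AT5G52810 (0.0509) and AT4G14090 (0.128) were not. WRKY53 lost its call in 3 fits without 1 array (highest adjusted p 0.0864) and UGT74B1 in 4 (0.111).

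The mutants shared much of their change. Of the probe sets called in camta1/3, 487 (97.0%) were also called in the same direction in camta2/3 and 1 in the opposite one, and 2164 (94.0%) of those called in camta2/3 were called in the same direction in camta1/2/3. Independent lists would share 17.5 higher and 6.78 lower for the first pair, where 371 and 116 were shared. Across probe sets, which are not independent replicates, the differences of camta1/3 and camta2/3 from WT had a Pearson correlation of 0.881. Unchanged groups with a shared WT group, all simulated from residuals permuted within each probe set, gave 0.498 and shared 0 calls. With nothing changed few calls could arise, so the 0 does not measure the part of shared controls in the overlap. Noise with shared controls gives such a correlation whatever its size, so 0.498 does not measure their part in the 0.881. The covariance, which keeps the size of the differences, was 0.139 against 0.0198 in the simulation. Scatter within groups, carried by shared controls, thus gave only a part of it. A deviation common to all 3 WT arrays was not simulated and is left open. The 487 became 226 without WT replicate 2, 275 without WT replicate 3, 162 without camta1/3 replicate 2 and 241 without camta1/3 replicate 3.

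The place of every array between the mutants was given by an index over 880 probe sets called higher and 773 called lower in camta1/2/3 than in camta1/2 at 22 °C, chosen without the WT, camta1/3 and camta2/3 arrays and after the data were seen. It sets camta1/2 at 0 and camta1/2/3 at 100 percent. WT at 22 °C stood at −17.1 ± 8.72, camta1/3 at 20.7 ± 4.53 and camta2/3 at 50.5 ± 3.39, and no array of 1 of these groups overlapped another group. At 4 °C, WT stood at −1.62 ± 6.32 and camta1/2/3 at 87.2 ± 7.47 (n = 3 arrays each).

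**Figure D4:**
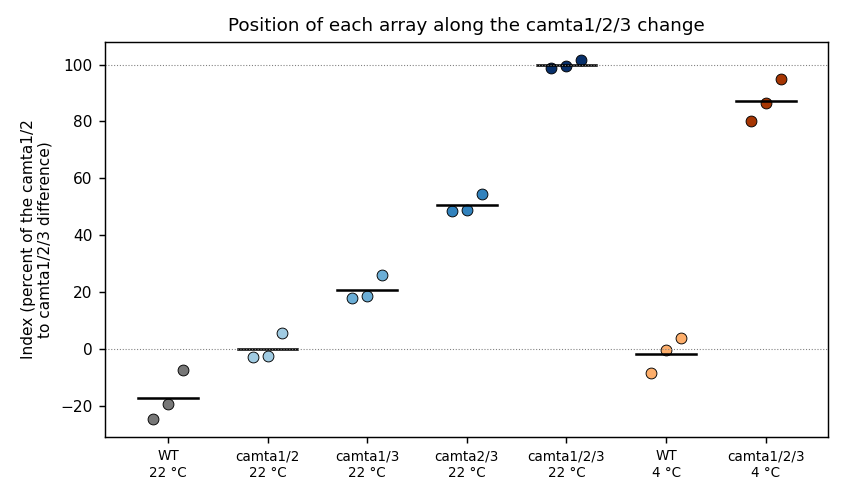
Index of each array (y axis, percent of the way from camta1/2 to camta1/2/3 at 22 °C) by group (x axis), with a dot for each of the 3 arrays of a group and a line at their mean. At 22 °C the arrays of WT, with a mean of −17.1, lie below those of camta1/3 at 20.7 and camta2/3 at 50.5.

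What each further mutation added was asked by comparing camta1/2/3 with the doubles at 22 °C. Against camta1/3, which differs by camta2, PDF1.4 was higher in camta1/2/3, at 8.13 ± 0.09 against 4.92 ± 0.48, and AT1G26250, an extensin-like gene, stood at 5.08 ± 0.24 against 2.33 ± 0.16. PDF1.2 was lower, at 3.89 ± 0.26 against 6.74 ± 0.40, and so was COR15A, at 5.08 ± 0.46 against 7.76 ± 0.97. The list of pattern-triggered immunity had 2 of 5 genes higher (2 when adjusted over the list alone), with BIK1 at 7.37 ± 0.18 against 6.21 ± 0.12 (list test, adjusted p = 0.000710). Of 5 flavonoid genes 2 were lower (3 when adjusted over the list alone), with UGT78D2 at 6.64 ± 0.09 against 7.27 ± 0.31 (list test, adjusted p = 0.0103, and adjusted p = 0.130 with an estimated correlation). The photosynthesis list was lower by its test (adjusted p = 0.0353, and adjusted p = 0.393 with an estimated correlation), while 0 of its 6 genes passed and 0 when adjusted over the list alone, RCA standing at 13.38 ± 0.18 against 13.60 ± 0.15. PYK10 was higher, as 1 of 3 root markers, at 8.83 ± 0.43 against 7.57 ± 0.46. Beside these groups the actin difference was 2.90 ± 0.13 against 2.48 ± 0.26. Called probe sets came to 2177, 1007 higher and 1170 lower, against 1437 without camta1/3 replicate 1 and 481 on the 6 arrays alone, where COR15A, UGT78D2, DFR, WRKY22 and PYK10 were not called. PYK10 lost its call in 3 fits without 1 array (highest adjusted p 0.0854), DFR in 4 (0.190) and with a replicate block (0.0548), and WRKY22 in 1 (0.0681).

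Against camta2/3, which differs by camta1, AT1G26250 was higher in camta1/2/3, at 5.08 ± 0.24 against 2.17 ± 0.00, as were PDF1.4, at 8.13 ± 0.09 against 5.97 ± 0.25, and the amido synthetase gene WES1 (AT4G27260), at 6.88 ± 0.46 against 4.92 ± 0.15. AT1G13650 was lower, at 6.60 ± 0.08 against 8.55 ± 0.36. COR15A stood at 5.08 ± 0.46 against 6.24 ± 0.55 (adjusted p = 0.430). Pattern-triggered immunity again had 1 of 5 genes higher, BIK1 (2 when adjusted over the list alone), at 7.37 ± 0.18 against 6.66 ± 0.05 (list test, adjusted p = 0.00883, and adjusted p = 0.0763 with an estimated correlation), and 0 of 5 flavonoid genes passed (0 when adjusted over the list alone). The root marker PYK10 was higher, at 8.83 ± 0.43 against 7.44 ± 0.19. The actin difference was 2.90 ± 0.13 against 2.62 ± 0.16, and PYK10 lost its call with it as a covariate (adjusted p = 0.0612) and in 5 fits without 1 array (highest 0.155). Of 326 called probe sets 229 were higher and 97 lower (70.2% higher, but 52.7% of 491 with quantile normalization), and 59 were called on the 6 arrays alone, without WES1, AT1G13650, BIK1 or PYK10. The count was 123 without camta2/3 replicate 2, 124 without camta2/3 replicate 3 and 179 without camta1/2/3 replicate 1.

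Against camta1/2, which differs by camta3, CCOAMT was higher in camta1/2/3, at 8.55 ± 0.33 against 4.04 ± 0.11, and the osmotin gene OSM34 (AT4G11650) stood at 8.19 ± 0.16 against 4.36 ± 0.73. AT2G39850 was lower, at 3.71 ± 0.37 against 6.88 ± 0.55, as were PDF1.2, at 3.89 ± 0.26 against 6.68 ± 0.34, and COR15A, at 5.08 ± 0.46 against 7.99 ± 0.95. Of 5 genes of pattern-triggered immunity 2 were higher (2 when adjusted over the list alone), BIK1 at 7.37 ± 0.18 against 6.01 ± 0.07 and WRKY22 at 4.14 ± 0.37 against 2.85 ± 0.01 (list test, adjusted p = 0.00178). Of 5 flavonoid genes 2 were lower (3 when adjusted over the list alone), with DFR at 4.86 ± 0.45 against 6.55 ± 0.44 (list test, adjusted p = 0.00499, and adjusted p = 0.0951 with an estimated correlation). Of 3 genes of glucosinolate synthesis 2 were lower (3 when adjusted over the list alone), with AT2G31790 at 7.22 ± 0.17 against 8.44 ± 0.10. The root marker PYK10 was higher, at 8.83 ± 0.43 against 7.19 ± 0.63. The actin difference was 2.90 ± 0.13 against 2.09 ± 0.05, and 2443 probe sets were called with it as a covariate. Without it 3533 were called, 1927 higher and 1606 lower (54.5% higher, but 49.8% with quantile normalization), and 1653 on the 6 arrays alone, where COR15A (adjusted p = 0.0577), DFR (0.0601), BCAT4 (0.0589) and PYK10 (0.0943) were not.

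The doubles that share camta3, camta1/3 and camta2/3, were compared last. SWEET17 (AT4G15920), a sugar transporter gene, was higher in camta1/3, at 8.25 ± 0.20 against 7.15 ± 0.23, and the nitrate transporter gene NRT2.5 (AT1G12940) was lower, at 3.01 ± 0.16 against 4.22 ± 0.16. AT5G61660 stood at 8.22 ± 0.15 against 6.43 ± 0.25. Of 5 genes of pattern-triggered immunity 0 passed (1 lower when adjusted over the list alone), BIK1 standing at 6.21 ± 0.12 against 6.66 ± 0.05, and the list was lower by its test (adjusted p = 0.00760, and adjusted p = 0.0506 with an estimated correlation). Of 5 flavonoid genes 0 passed (2 higher when adjusted over the list alone), with DFR at 6.05 ± 0.52 against 5.05 ± 0.24 (list test, higher, adjusted p = 0.00106, and adjusted p = 0.0506 with an estimated correlation), and the photosynthesis list was higher by its test with 0 of 6 genes called (0 when adjusted over the list alone, list test adjusted p = 0.0428, and adjusted p = 0.418 with an estimated correlation). For actin the 3′ to 5′ difference was 2.48 ± 0.26 in camta1/3 and 2.62 ± 0.16 in camta2/3. Only 24 probe sets were called, 17 higher and 7 lower in camta1/3, and 3 on the 6 arrays alone, none of them a gene named here. The count was 2 without camta1/3 replicate 1, 13 without replicate 3, 14 without camta2/3 replicate 2 and 8 without replicate 3, and the calls of SWEET17, AT5G61660 and NRT2.5 were lost in 4, 1 and 1 of these fits (highest adjusted p 0.127, 0.0557 and 0.0729).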

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

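The split test of the interaction with additive effects taken out and the 3 tests of the order of the mutants were chosen after the result was seen, and the other tests before.

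The cold response differed between camta1/2/3 and WT for 447 probe sets by the interaction test, and for 275 without WT replicate 2 at 22 °C. The interaction is the response of camta1/2/3 minus that of WT (log2), so that a positive value can be a larger rise or a smaller fall. It was 4.15 for COR15A, which rose more in camta1/2/3, and 2.80 for PDF2.1, which rose more as well. AT1G32950 (2.83), LEA4-5 (−4.04) and AT2G24560 (−3.92) lay at the floor at 22 °C in both genotypes, so their rises are not measured and only the levels at 4 °C differ, higher in camta1/2/3 for AT1G32950 and lower for the other genes. For AT1G13650 (3.10), AT1G23390 (1.75), AT5G14120 (1.69), AT4G33666 (1.55) and AT3G23080 (1.25) both genotypes fell and camta1/2/3 fell less. AT1G13650 held the same value on all WT arrays at 4 °C, as at a floor, and started lower at 22 °C in camta1/2/3. Its smaller fall may thus only reflect that lower start. For AT1G07440 (3.11) and THI2.1 (0.62) the response was below 0 in WT and above 0 in camta1/2/3. Of the other negative values, EXLA1 (−2.44) went up less in camta1/2/3, AT1G72060 (−2.48), PDF1.4 (−2.44) and AT5G19120 (−1.67) went down more, and LUP5 (−2.53) went down in camta1/2/3 with about no difference in WT. LUP5 lost its call in 3 of 12 fits without 1 array (highest adjusted p 0.0603), AT1G72060 in 8 (0.0916), EXLA1 in 8 (0.0732) and THI2.1 in 10 (0.0718).

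Weak RNA of replicate 2 of camta1/2/3 at 4 °C, whose actin 3′ to 5′ difference was 4.25, would have shrunk these interactions when that array was left out. The median ratio without to with it was 1 (interquartile range 0.944 to 1.05), and 329 of the 447 kept their call. Without replicate 2 of camta1/2/3 at both temperatures, 470 probe sets were called, and only 287 of them were among the 447. Compression of dim values at the floor, as the source of most calls, would have needed most of the probe sets to lie under 3 in some group. Of those called 23.9% did, against 31.4% of all probe sets. The test does not clear the 107 called probe sets under 3, or any with a floor above 3. Whether the difference arose at 22 °C or at 4 °C cannot be told apart, since 53.0% of the probe sets differed more at 22 °C, with a 95% interval of 48.3% to 57.7% that takes probe sets of the same arrays as independent and leaves out the variation between arrays. Of 100 drawn splits of genotype within each temperature, 6 gave as many calls as the real 188. By this test, chosen before the result was seen, an accidental grouping of arrays is left open as a source of the calls. The highest count, 6414, came when the genotypes were swapped at 4 °C alone, which points to the structure of the genotypes for that split. The source of the other high counts was not tested. With the additive effects of genotype and temperature taken out, the real split still gave 188. It was the 1 of 100 with as many, and the highest other gave 3. Those effects were set by the real groups, and this version was chosen later, so it does not settle the question.

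The actin difference of 2.90 as a mean of camta1/2/3 at 22 °C stood above the 2.23 of WT, outside the main measurement. On the index of change, which sets camta1/2/3 at 100 by its construction, WT, camta1/3 and camta2/3 took that order. The smallest gap between camta2/3 and camta1/3 arrays or camta1/3 and WT arrays was 22.5 percent, that between camta2/3 and camta1/3. No WT array entered the choice of probe sets or that gap, so noise of the WT arrays could not set the order of these doubles. The place of WT still rests on its 3 arrays, at −24.5 to −7.50, below the lowest camta1/3 array at 17.8. The groups' actin difference took the same order, 0.68 higher in camta1/2/3 than in WT (log2), so RNA integrity may account for part of the change. The other control pairs did not take that order in full. For GAPDH the 3′ to 5′ difference was 0.05 ± 0.11 in WT, −0.08 ± 0.16 in camta1/3, 0.37 ± 0.15 in camta2/3 and 0.23 ± 0.04 in camta1/2/3 at 22 °C. For ubiquitin it was 0.65 ± 0.11, 0.79 ± 0.20, 0.76 ± 0.38 and 1.06 ± 0.14 in the same groups. Ubiquitin was thus, like actin, lowest in WT and highest in camta1/2/3 of these groups, and its camta1/3 and camta2/3 values differed by less than their SD. With actin as a covariate, 96.0% of the difference of the index between camta2/3 and WT was kept (94.4% to 96.8% without 1 array). The slope for actin in that fit comes from scatter within groups, and the steps between the mutants were not fitted. The fit therefore cannot decide whether RNA integrity accounts for the order. Which CAMTA genes were mutated, the difference that the design names, stays open and untested.

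COR15A was 15.1-fold lower in camta1/2/3 than in WT at 22 °C. If cold-induced genes as a class stood lower in camta1/2/3, the 469 named genes that rose at least 2-fold in WT would lie below random lists of like level in camta1/2/3 against camta1/2. Their median was −0.01, inside the −0.04 to 0.02 of the random lists, 40.1% of which lay as low or lower; 42 of the 469 were called lower and 65 higher. Against WT, whose arrays also served to choose these genes, their median was −0.03, with 64 called lower and 87 higher. These values argue against a lower level of the 469 genes as a whole. They do not speak for the smaller list of 6 COR and CBF regulon genes. Its median against WT at 22 °C was −0.69, with 2 genes called lower, and its list test did not pass (adjusted p = 0.0877). No other explanation for COR15A was tested.

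Other splits of the 6 arrays of a pair of groups number 10, too few for a share under 0.05. In the fits on those arrays the real split alone, 1 of 10, gave as many calls for WT at 4 °C against 22 °C (3131, highest other 0), camta1/2/3 at 4 °C against 22 °C (2447 and 0), camta1/2/3 against WT at 4 °C (2014 and 1) and at 22 °C (3252 and 0) and camta2/3 against WT (1262 and 0). The same held for camta1/2/3 against camta1/3 (481 and 4), camta2/3 (59 and 1) and camta1/2 (1653 and 1), and for camta1/3 against camta2/3 (3 and 0). For camta1/2 against WT, 10 of 10 splits gave at least the 0 of the real one by limma, where 1491 probe sets had an unadjusted p under 0.05, and the highest other gave 2. For camta1/3 against WT, 2 of 10 gave the 1 call of the real split, the highest other being 1.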

How the results depend on the processing

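Of 8471 values of named genes under the alternatives, 533 lost their call, 79 gained one and 7859 were counted as unchanged. For the list tests these numbers were 17, 8 and 263 of 288. Among values called as reported or under the alternative, 0 changed direction, for genes and for lists. A value called in neither fit was counted as unchanged whatever its direction. The counts below follow 1 order: WT at 4 °C against 22 °C, camta1/2/3 likewise, the interaction, camta1/2/3 against WT at 4 °C and at 22 °C, camta1/2, camta1/3 and camta2/3 against WT, camta1/2/3 against camta1/3, camta2/3 and camta1/2, and camta1/3 against camta2/3. With only the arrays of the groups compared, and so fewer arrays to estimate the spread, they were 3131, 2447, 188, 2014, 3252, 0 (by limma, with 1491 at an unadjusted p under 0.05), 1, 1262, 481, 59, 1653 and 3, and 3.06% of the cold-induced and 4.51% of the cold-repressed probe sets responded less in camta1/2/3. At least 2-fold differences numbered 2038, 1881, 297, 1802, 2149, 23, 298, 949, 781, 143, 1304 and 11. Under an adjusted p of 0.01 the counts were 3306, 3110, 134, 2859, 3443, 4, 156, 1138, 948, 99, 1876 and 5. With 1 probe set per gene, and so fewer tested, they were 2831, 2684, 210, 2375, 2627, 13, 188, 1091, 1024, 143, 1716 and 12. The 487 shared by camta1/3 and camta2/3 became 291 at 2-fold and 184 with 1 probe set per gene. With a replicate block the counts were 5575, 5349, 491, 5149, 5710, 26, 540, 2583, 2548, 429, 3929 and 49. Array weights gave 128, 1006 and 3808 for camta1/2, camta1/3 and camta2/3 against WT, 3935 and 2115 for camta1/2/3 against camta1/3 and camta2/3, and 164 for camta1/3 against camta2/3. For camta1/2 against WT the count was 68 with quantile normalization, 56 with centring, 141 and 144 with the filters on level and 64 with trended and robust variances, and for camta1/2/3 against camta2/3 it was 491 with quantile normalization. With the actin covariate 2692 probe sets differed between camta1/2/3 and WT at 4 °C. Without both arrays in doubt the share of cold-repressed probe sets that fell less was 5.45%. Of the 60 list tests 14 were called with an estimated correlation, and 13 of the 48 that were left by the filter on the mean level. Except for the smaller numbers of arrays, probe sets or lists, the cause was not tested. The actin covariate, the fit without both arrays in doubt and the families were chosen after seeing the data.

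Without 1 array, in the same order, the counts ran from 4206 to 4794, 3909 to 4663, 275 to 555, 3590 to 4526, 4198 to 5134, 7 to 279, 169 to 718, 1485 to 2314, 1437 to 1843, 123 to 310, 2534 to 3147 and 2 to 25. The cold-induced share ran from 4.96% to 9.61%, the cold-repressed one from 5.31% to 10.4% and the 487 shared calls from 162 to 692. Signal over background limited dim genes: 59.8% to 60.7% of the probe sets lay over 4 on an array.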

Other observations

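Gene families, set by their symbols after the values were held, and the tests of them under other settings were chosen after the data were seen. Families were tested in the same way as the lists, and the genes named from them were chosen after their values were seen. Of 8 autophagy (ATG) genes 5 were higher in camta1/2/3 than in WT at 22 °C and 5 at 4 °C, and 0 were lower (family test, adjusted p = 0.00252 and 0.000418, but 0.220 and 0.346 with an estimated correlation). ATG8B (AT4G04620) stood at 7.43 ± 0.14 against 5.72 ± 0.19 at 22 °C and at 8.15 ± 0.54 against 6.25 ± 0.09 at 4 °C, and ATG8E (AT2G45170) at 7.58 ± 0.57 against 5.83 ± 0.30 and at 6.14 ± 0.17 against 4.90 ± 0.13 (log2, n = 3 each). Of 7 tubulin genes 4 were lower at 22 °C and 5 at 4 °C (adjusted p = 0.0389 and 0.0243, but 0.279 and 0.346 with an estimated correlation), and TUB6 (AT5G12250) stood at 8.48 ± 0.06 against 9.24 ± 0.18 and at 7.46 ± 0.42 against 8.49 ± 0.10. The actin difference moved with both families, at 2.90 ± 0.13 in camta1/2/3 against 2.23 ± 0.21 in WT at 22 °C and 3.11 ± 1.0 against 2.00 ± 0.62 at 4 °C. With it as a covariate 4 and 3 autophagy genes stayed higher and 3 and 1 tubulin genes lower, at 22 °C and 4 °C, and no called member changed direction with quantile normalization, centring on the median or array weights.

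Of 12 genes of RNA polymerase subunits 6 rose at 4 °C in WT and 6 in camta1/2/3 (family test, adjusted p = 0.00722 and 0.0373, and adjusted p = 0.657 and 0.704 with an estimated correlation). NRPB7 (AT5G59180) went from 6.43 ± 0.16 to 7.28 ± 0.13 in WT and from 5.79 ± 0.15 to 6.83 ± 0.47 in camta1/2/3. Among 6 WRKY genes 4 were higher in camta1/2/3 than in WT at 22 °C (adjusted p = 0.00626, and adjusted p = 0.159 with an estimated correlation), and WRKY47 (AT4G01720) stood at 6.39 ± 0.07 against 4.39 ± 0.34. In camta2/3 against WT, 4 of 14 SWEET sugar transporter genes were lower and 1 higher (3 lower with each array centred on its median; adjusted p = 0.0431, and adjusted p = 0.194 with an estimated correlation). Of 360 family tests 25 were called, and 0 by camera with an estimated correlation.

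Of the tests in this paragraph, the one with camta1/2/3 was chosen after the result of the one with camta2/3 was seen. The hypothesis was that loss of CAMTA3 and cold move the same genes in opposite directions, which needed a correlation under −0.1. Across 22746 probe sets, which are not independent replicates, the difference between camta2/3 and camta1/2 had a Pearson correlation of 0.135 with the WT cold response (Spearman 0.142), but it swaps CAMTA1 as well as CAMTA3 and so leaves the hypothesis open. The difference between camta1/2/3 and camta1/2, which is by camta3 alone and shares no array with the WT cold response, had a correlation of 0.114 (Spearman 0.123), where opposite directions needed a negative one.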
